A study of Homo sapiens with 4 samples.

How the data were processed

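Gene expression was measured by RNA sequencing in 4 libraries of BeWo cells, 2 with a control hairpin and 2 with a hairpin against GPX4, after ferrostatin-1 withdrawal. Per the labels' protocols, RNA was isolated with a column kit, libraries were made with standard Illumina methods, and paired-end reads were obtained on a NovaSeq instrument. Whether RNA was selected by poly(A) tail or by removal of ribosomal RNA is not given in the sources used here. Per the submitters' processing notes, GRCh38, STAR 2.5.2a and DESeq2 were used, with no role or order named. The annotation release, the counting tool and its strand setting are not given in the sources used here. The authors deposited a table of raw counts per gene for 58884 Ensembl gene IDs, 1 column per library, with no rows of unassigned reads. A gene without strand-specific counting shares reads with an overlapping gene on the opposite strand, and near-identical gene copies share reads, so such genes are named as uncertain.

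Of the IDs, 58611 matched GENCODE release 29 on GRCh38, which gave coordinates, and 58472 matched a table of current names. A name from either was found for 42371 IDs. Library totals ranged from 18926983 to 22971448 counts. A gene was tested when edgeR's filterByExpr kept it (minimum count 10), which left 16452 genes holding 99.81% to 99.89% of the counts in each library.

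The planned main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of shGPX4 against shControl with TMM scaling and no block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It leaves 2 residual degrees of freedom, and the fit with a block leaves 1. Levels are CPM on TMM-scaled library sizes. Within-experiment fold changes are differences of log2 CPM between 2 libraries with a prior count of 2, and they have no replicate check. Errors are SD between libraries or SE from the fit. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, and also with an estimated correlation and with fry's directional test. There were 27 lists, 5 of them primary, and the 24 with at least 5 tested members were tested and adjusted together. A list's median within an experiment was placed among 10000 random lists of the same size, matched on mean expression in 50 bins, as a description of those libraries. Groups, the main test, the alternatives other than those named as added, and the lists were chosen before the data were examined.

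The titles give each group a library A and a library B after an abbreviation read as experiment, so the letters pair the libraries by shared experiment. Libraries of the same letter deviated together from their group means, with a correlation of 0.821 across genes, and the first principal component (83.3% of variance) separated the letters. The biological coefficient of variation was 63.1% without the block and 24.9% with it. Fits with the letter as a block are therefore given beside the planned ones where they change a call. DESeq2 1.42.0 and limma-voom with the block, camera with the block and an estimated correlation, and tests of protein-coding genes alone were added after the data were seen.

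The rule for named genes took GPX4, then up to 8 genes per direction past the main threshold, which gave none, then from each primary list the 2 members with the smallest p, given as values. A rule added after the data were seen took, by DESeq2 with the block, the 12 genes with the highest and the 12 with the lowest log2 fold change among those past the threshold with a symbol, a mean of at least 5 CPM and the same direction in both experiments. Other list members were named as examples after their values were seen.

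The tests were tried on simulated counts for 16452 genes with the real libraries' means, pairing and depths, 200 genes changed and 10 simulations. For the comparison of shGPX4 with shControl, edgeR without the block recovered 0% of genes changed 2-fold, 4-fold or 8-fold. With the block edgeR recovered 34.6%, 92.4% and 99.1%, with 2.97% of calls false. DESeq2 with the block recovered 30.6%, 88.4% and 98.0%, with 1.57% false, and limma-voom with the block recovered 31.6%, 91.9% and 99.1%, with 4.88% false. With no gene changed, each test called a mean of 0 genes. Each changed gene had the same fold in both simulated experiments, and its spread followed the trend on expression alone. In the real libraries the log2 fold changes of the experiments correlated at 0.0358. The recovered and false shares therefore describe the simulated setting and may not hold for these libraries. The preset camera test called a shifted list of 30 genes in 10 of 10 simulations and 0 of 380 other lists. In the real libraries the estimated correlation between list members was 0.62 for the ATF4 and amino acid response list. It was 0.26 for the syncytiotrophoblast list and -0.038 for the extravillous trophoblast list. The first 2 values exceed the preset correlation. The simulated calls therefore do not show that preset p-values hold for lists with correlated members. The alternatives covered scaling, test, filter on low counts, block, depth, gene set test, a minimum fold of 1.5 and leaving out each library in turn. Leaving out 1 library without a block sets unequal mixes of experiments A and B against each other, so such values include part of the difference between experiments. Replicate error rests on 2 libraries per group. Some named levels also rest on few counts, with 3 counts of HSD11B2 and 12 of HSPB1 in shGPX4 A, 3 of AFAP1L2 and 5 of BIRC7 in shControl B, and 13 of TREML2 in shGPX4 B.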

Results

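RNA sequencing was performed on 4 libraries of BeWo cells, a human placental choriocarcinoma line used as a model of villous trophoblast. The cells stably expressed a control short hairpin RNA (shControl, n = 2) or a hairpin against GPX4 (shGPX4, n = 2). GPX4 is the glutathione peroxidase that reduces lipid hydroperoxides in membranes, and its loss permits ferroptosis, an iron-dependent cell death driven by lipid peroxidation. The cells had been kept in ferrostatin-1, a radical-trapping inhibitor of ferroptosis, and were sequenced after its withdrawal. The comparison asks how trophoblast gene expression differs when ferroptosis is stimulated below a lethal level. Each group holds a library titled A and a library titled B, and the letter is read here as the experiment. Total counts were 21380168 in shControl A, 19851778 in shGPX4 A, 18926983 in shControl B and 22971448 in shGPX4 B. At least 1 count was recorded for 26421, 26384, 24287 and 23791 genes, in the same order.

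The RNA classes captured differed between the experiments more than between the hairpins. The signal recognition particle RNAs RN7SL1 and RN7SL2 took 8.97% and 7.58% of counts in shControl A and shGPX4 A, and 0.116% and 0.188% in shControl B and shGPX4 B. Replication-dependent histone genes, whose mRNAs end in a stem-loop and not a poly(A) tail, took 0.536% and 0.604% in experiment A and 0.00515% and 0.00427% in experiment B. Mitochondrially encoded genes took 0.305% and 0.334% in experiment A and 3.63% and 3.87% in experiment B. Across genes, which are not independent replicates, log2 CPM (counts scaled to a common library total) correlated at r = 0.980 between the 2 libraries of experiment A and at r = 0.975 in experiment B. The correlation was 0.878 between the 2 shControl libraries and 0.884 between the 2 shGPX4 libraries.

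GPX4 itself (ENSG00000167468, GRCh38 chromosome 19, 1103926 to 1106791, plus strand) was lower in the shGPX4 library of both experiments. Its TMM-scaled level was 163 CPM in shControl A and 9.18 CPM in shGPX4 A, a 17.6-fold difference on 3568 and 192 counts. In experiment B it was 280 CPM in shControl and 52.5 CPM in shGPX4, a 5.32-fold difference on 5217 and 1128 counts. The group means were 221 ± 82.4 CPM in shControl (SD, n = 2) and 30.9 ± 30.6 CPM in shGPX4 (SD, n = 2). The planned edgeR quasi-likelihood test, which did not use the experiment as a block, gave a log2 fold change of -2.84 ± 0.91 (SE), an unadjusted p of 0.0251 and a Benjamini-Hochberg adjusted p of 0.9999. With the experiment as a block the edgeR value was -3.26 ± 0.40 (SE, adjusted p = 0.134). DESeq2 with the same block gave -3.26 ± 0.39 (SE, adjusted p = 5.14e-13).

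Other genes were higher in the shGPX4 library of both experiments. HAND1, a transcription factor of trophoblast and heart, COL6A3, a collagen VI chain, and C3, the central complement component, were among the genes with the highest fold. HAND1 (ENSG00000113196, chromosome 5, 154474972 to 154478264, minus strand) went from 37.5 to 185 CPM in experiment A and from 3.43 to 74.3 CPM in experiment B. COL6A3 (ENSG00000163359, chromosome 2, 237324003 to 237414375, minus strand) went from 117 to 536 CPM and from 10.9 to 206 CPM. C3 (ENSG00000125730, chromosome 19, 6677704 to 6730562, minus strand) went from 8.73 to 62.1 CPM and from 3.81 to 28.4 CPM. Their log2 fold changes by DESeq2 with the block were 3.34 ± 0.43, 3.21 ± 0.40 and 2.88 ± 0.36 (SE), with adjusted p of 2.87e-11, 9.90e-12 and 9.90e-12. The adaptor gene AFAP1L2 had a log2 fold change of 3.33 by the same fit, on 60 and 240 counts in experiment A and 3 and 125 counts in experiment B. SMTNL2 had 2.72 (2.56 within experiment A and 2.75 within experiment B). MYL7, the atrial myosin regulatory light chain, had 2.55 (1.81 and 3.26), and BIRC7, an inhibitor of apoptosis protein, had 2.45. The secreted angiopoietin-like protein gene ANGPTL2 had 2.36 (1.64 and 3.04), the orphan receptor gene GPRC5B 2.24 (1.40 and 2.96) and PRTG, which encodes protogenin, 2.02 (25.2 to 143 CPM and 18.8 to 53.5 CPM). The collagen V chain gene COL5A1 had 1.95 (1.61 and 2.27) and the actin and phosphatase regulator gene PHACTR1 had 1.91 (1.98 and 1.73). BIRC7 was expressed mainly in experiment A, at 9.19 and 49.8 CPM against 0.268 and 1.49 CPM in experiment B, and it was 5.37-fold and 4.35-fold higher in shGPX4 within the experiments. Without shGPX4 A and with no block, which sets both shControl libraries against shGPX4 B alone, its edgeR log2 fold change was -1.65. Such unblocked fits mix the experiments unequally, and with 1 library left out other edgeR values ranged widely. The lowest value, without shControl B, and the highest, without shControl A, were 1.80 and 5.24 for HAND1, 1.66 and 5.70 for AFAP1L2, 1.67 and 5.09 for COL6A3 and 1.47 and 3.85 for MYL7. They were 1.03 and 3.05 for COL5A1 and 0.29 and 3.45 for PHACTR1, without shGPX4 A and without shControl A. PRTG had 1.30 without shGPX4 A and 2.69 without shGPX4 B, and the highest value of BIRC7 was 6.54, without shControl A.

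Among the genes lower in shGPX4 cells were a steroid hormone enzyme, a placental surface receptor and a glutathione-degrading enzyme. CYP19A1 (ENSG00000137869, chromosome 15, 51208057 to 51338610, minus strand), the aromatase that makes estrogens, went from 150 to 10.1 CPM in experiment A and from 14.9 to 6.61 CPM in experiment B. TREML2 (ENSG00000112195, chromosome 6, 41190277 to 41201194, minus strand) went from 38.3 to 2.01 CPM and from 2.36 to 0.605 CPM. CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519, plus strand), which degrades glutathione and is induced by ATF4, went from 5.76 to 1.86 CPM and from 42.9 to 3.26 CPM. Their DESeq2 log2 fold changes with the block were -2.54 ± 0.50, -3.23 ± 0.61 and -2.69 ± 0.53 (SE), with adjusted p of 0.000420, 0.000158 and 0.000477. EFR3B had a log2 fold change of -2.80 (-1.67 within experiment A and -3.64 within experiment B), the adaptor gene SH3BP2 -2.13 (-1.36 and -2.88) and MME, which encodes the peptidase neprilysin, -2.08 (-1.94 and -2.18). The peptide hormone gene ADM2 had -1.98 (-0.77 and -3.13) and the lysosomal GTPase gene ARL8A -1.97 (-1.22 and -2.68). The lectin receptor gene CLEC1A had -1.79 (-2.01 and -1.58) and the stress-induced chromatin protein gene NUPR1 -1.78 (-0.93 and -2.65). The small heat shock protein gene HSPB8 had -1.76 (-2.73 and -0.83) and the adenylyl cyclase gene ADCY1 -1.67 (-1.54 and -1.80). In unblocked edgeR fits with 1 library left out, the value nearest 0, without shControl B, and the largest, without shControl A, were -1.15 and -4.06 for CHAC1, -1.25 and -2.99 for SH3BP2, -0.34 and -3.47 for ADM2, -1.16 and -2.76 for ARL8A and -1.02 and -2.55 for NUPR1. EFR3B had -0.78 without shControl B and -4.37 without shGPX4 B, and HSPB8 had -1.07 without shGPX4 A and -2.53 without shGPX4 B. Without shControl A the value was -0.85 for TREML2 and -0.83 for CYP19A1, against -5.05 for TREML2 without shGPX4 A and -4.15 for CYP19A1 without shControl B.

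By DESeq2 with the block, a fit added after the data were seen, 32 genes were higher and 26 lower in shGPX4 at an adjusted p under 0.05, among 14494 genes with an adjusted p. An unadjusted p under 0.05 was found for 554 of those genes, where uniform p-values would give 725. Of these 58 genes, 56 were protein-coding and 57 had an unadjusted p under 0.05 in edgeR with the block. The planned edgeR test called 0 genes higher and 0 lower among 16452, with 88 genes at an unadjusted p under 0.05 where uniform p-values would give 823. With the block edgeR called 1 gene, C3 (log2 fold change 2.86, adjusted p = 0.0361), with 844 genes at an unadjusted p under 0.05, again against 823. Among protein-coding genes alone, edgeR with the block called 0 genes, so the C3 call was lost there. DESeq2 without the block called 0 genes (166 unadjusted), and limma-voom called 0 both without the block (82 unadjusted) and with it (918 unadjusted, against 823). The 24 genes named above besides GPX4 therefore rest on 1 tool, except C3, whose edgeR call depended on the set of genes tested. The p-values measure only the spread between these libraries. GPRC5B, PRTG, PHACTR1, CYP19A1, MME and ARL8A overlap an exon of a gene on the opposite strand, and the strand setting of the counts is not given in the sources used here.

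**Figure D1:**
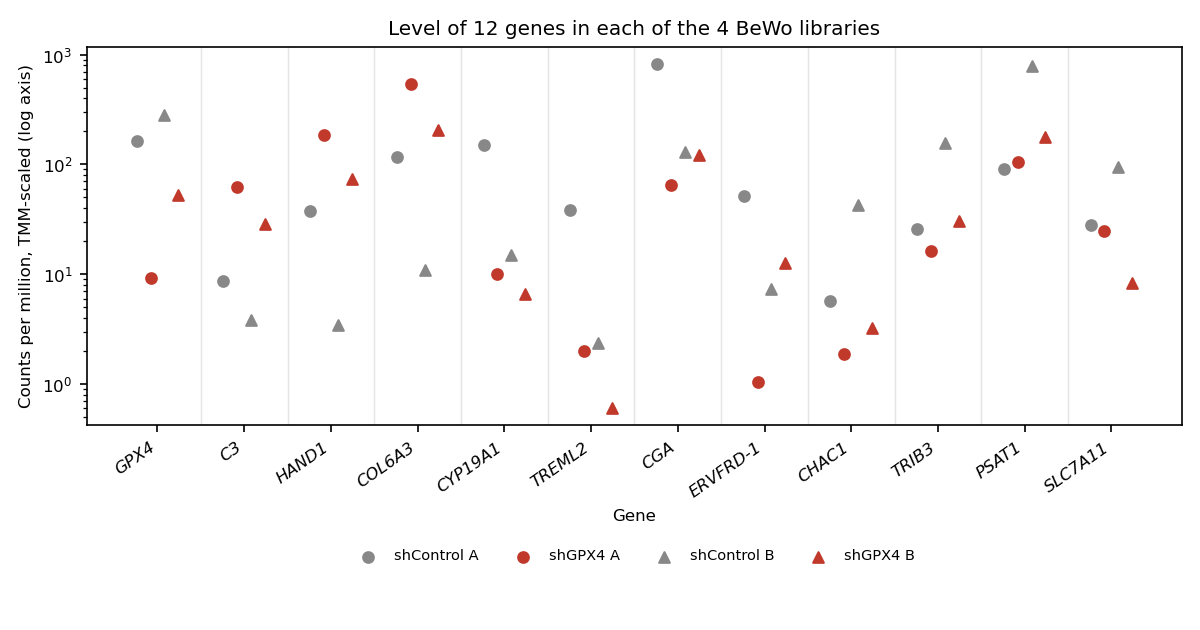
TMM-scaled CPM (log axis) of 12 genes in each library, grey for shControl and red for shGPX4, circles for experiment A and triangles for experiment B. GPX4 was lower and C3, HAND1 and COL6A3 were higher in shGPX4 in both experiments, whereas CGA went from 816 to 65.2 CPM in experiment A and from 131 to 121 CPM in experiment B.

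Fold changes were compared between the experiments, each with 1 library per arm and so no replicate check of its own. Across genes, the log2 fold changes of experiments A and B correlated at r = 0.0358. Among 10605 genes with a mean of at least 5 CPM, 161 were at least 2-fold higher in shGPX4 in experiment A and 237 in experiment B, and 37 were so in both, where independent lists would share 3.60. For genes at least 2-fold lower the numbers were 229, 366 and 36, with 7.90 for independent lists. A further 36 genes moved at least 2-fold in opposite directions, with 10.7 for independent lists. Because this overlap also exceeded its value for independent lists, the overlaps of shared direction alone do not show a shared response to the hairpin.

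**Figure D2:**
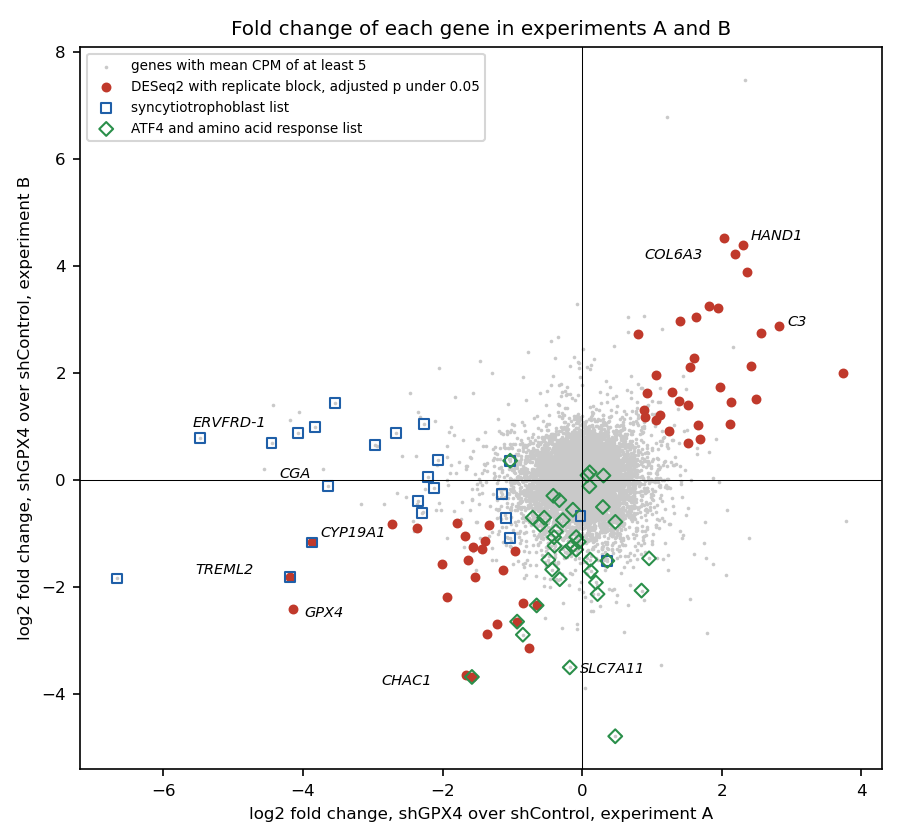
Log2 fold change of shGPX4 over shControl in experiment A (x axis) and experiment B (y axis) for 10605 genes (grey), with the 57 edgeR-tested genes past the DESeq2 threshold with the block in red, the syncytiotrophoblast list as blue squares and the ATF4 list as green diamonds. Genes in red lie in the 2 quadrants of shared direction, most squares lie to the left of 0 along the x axis, and most diamonds lie below 0 along the y axis. The fit with the block favours genes of shared direction, so the place of the red genes follows in part from their selection.

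Apart from GPX4, CHAC1 was the only member of the ferroptosis lists past the DESeq2 threshold with the block. In the simulations this test recovered 30.6% of 2-fold changes, so members that did not pass are not shown to be unchanged. Of 30 tested ferroptosis suppressors, GPX4 was the 1 member past the DESeq2 threshold with the block, over all genes and adjusted over the list alone. HSPB1, a small heat shock protein gene, was at 5.08 and 2.84 CPM in shControl A and B and at 0.574 and 1.12 CPM in shGPX4 A and B (edgeR adjusted p = 0.9999). SLC7A11, the cystine transporter that supplies glutathione synthesis, was at 28.1 and 24.9 CPM in shControl and shGPX4 of experiment A and at 95.3 and 8.33 CPM in experiment B. The list's median log2 fold change was -0.047, with a camera adjusted p of 0.470. Without shGPX4 B the list's median was -0.30. GPX4, the gene targeted by the hairpin, counts as a member in these values, and the list was not tested without it. Of 28 tested ferroptosis promoters and markers, CHAC1 was the 1 member past the DESeq2 threshold with the block, over all genes and adjusted over the list alone, and it was lower. SAT1, the spermidine acetyltransferase gene, was at 67.0 and 60.1 CPM in shControl and 93.7 and 83.3 CPM in shGPX4 (edgeR log2 fold change 0.48, adjusted p = 0.9999). This list had a median of 0.057, a mean of -0.079 and a camera adjusted p of 0.860 in the upward direction.

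Genes of the ATF4 and amino acid response were lower in shGPX4 as a group, mostly in experiment B. The median log2 fold change of the 39 tested members was -0.84 (camera adjusted p = 1.03e-11 with the preset correlation, adjusted p = 0.906 with an estimated correlation and 0.984 by fry). Members past the DESeq2 threshold with the block were CHAC1, NUPR1 and TRIB3, all lower, and 9 were lower when adjusted over the list alone, against 4 by edgeR with the block adjusted over the list alone. TRIB3, a pseudokinase gene, went from 25.7 to 16.4 CPM in experiment A and from 156 to 30.6 CPM in experiment B. PSAT1, a serine synthesis enzyme gene, was at 90.5 and 106 CPM in experiment A and at 784 and 179 CPM in experiment B. ATF4 itself was at 410 and 506 CPM in experiment A and at 562 and 596 CPM in experiment B. In experiment A the list's median was -0.18, at percentile 1.53 of 10000 random lists matched on expression, and in experiment B it was -1.24, at percentile 0. Other lists were about as low in experiment A, at percentile 1.22 for ferroptosis suppressors, 0.36 for iron handling and 1.76 for ER chaperones. The value in experiment A is thus not particular to the ATF4 list. Without shControl B the list had a median of 0.0012 and an adjusted p of 0.920.

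Syncytiotrophoblast genes, which mark the fused hormone-secreting layer of the placenta, were lower in shGPX4 as a group, mostly in experiment A. The median log2 fold change of the 34 tested members was -0.99 (camera adjusted p = 5.27e-10 with the preset correlation, adjusted p = 0.906 with an estimated correlation and 0.984 by fry). CYP19A1 and TREML2 passed the DESeq2 threshold with the block, 7 members were lower when adjusted over the list alone, and edgeR with the block gave 9 lower when adjusted over the list alone. HSD11B2, which inactivates cortisol, was at 24.3 and 0.143 CPM (531 and 3 counts) in experiment A and at 6.92 and 1.86 CPM in experiment B, and it overlaps an exon on the opposite strand. CGA, the alpha subunit of chorionic gonadotropin, was at 816 and 65.2 CPM in experiment A and at 131 and 121 CPM in experiment B. ERVFRD-1, the fusion protein syncytin-2, was at 51.2 and 1.05 CPM in experiment A and at 7.29 and 12.7 CPM in experiment B. In experiment A the list's median was -2.10, at percentile 0 of the random matched lists, and in experiment B it was 0, at percentile 55.7. Of the 34 tested members, 16 were lower in experiment B. A value of exactly 0 is what a member with no counts in either library of an experiment gives. The median in experiment B therefore does not show that expressed members were unchanged there. Without shControl A the list had a median of -0.0097 and an adjusted p of 0.144, and levels of the CGB and PSG genes are uncertain because near-identical copies share reads.

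Cytotrophoblast and stem genes did not pass as a group (27 tested members, median 0.092, camera adjusted p = 0.234). Their median was 0.038 in experiment A (percentile 85.95 of random matched lists) and 0.23 in experiment B (percentile 92.39). VGLL1, a cofactor of TEAD transcription factors, was at 23.3 and 45.2 CPM in shControl A and B and at 12.2 and 15.7 CPM in shGPX4 A and B. It passed adjusted over the list alone with the block in both edgeR and DESeq2, and not over all genes (edgeR adjusted p = 0.384, DESeq2 adjusted p = 0.167). ELF5, a trophoblast stem cell factor, was at 4.80 and 3.78 CPM in experiment A and at 2.14 and 14.2 CPM in experiment B. The list passed without shGPX4 A (median 0.36, adjusted p = 0.00492) and without shControl B (median 0.53, adjusted p = 0.0453).

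Extravillous trophoblast genes, which mark the invasive lineage, had a median below 0 in both experiments. Of the 27 tested members, 18 were lower in experiment A, 20 in experiment B and 13 in both, and 2 were higher in both. Independent experiments with those numbers could give such an overlap, so it does not show that the same members fell. The members had a median of -0.39 in experiment A (percentile 0) and -0.46 in experiment B (percentile 0.01). The joint median was -0.38 (camera adjusted p = 0.000980, adjusted p = 0.906 with an estimated correlation and 0.984 by fry). With the block the adjusted p was 0.000236 by preset camera, 0.942 with an estimated correlation and 0.0397 by fry. No member passed over all genes, and 1 was lower by DESeq2 with the block adjusted over the list alone. The integrin gene ITGA5 was at 99.1 and 61.3 CPM in experiment A and at 113 and 55.5 CPM in experiment B, and the serine protease gene HTRA4 was at 214 and 60.2 CPM and at 82.1 and 54.8 CPM. The preset camera call was lost without shControl A (median -0.12, adjusted p = 0.442), without shGPX4 A (-0.44, 0.108), without shGPX4 B (-0.64, 0.0976) and with no filter on low counts (-0.22, 0.0806).

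The cholesterol synthesis, proliferation, oxidative phosphorylation and hypoxia lists passed in the upward direction with the preset correlation, but for each the adjusted p was 0.906 with an estimated correlation and 0.984 by fry. Cholesterol synthesis genes had a median of 0.37 over 25 members (adjusted p = 3.55e-05), from -0.040 in experiment A (percentile 48.5 of random matched lists) and 0.69 in experiment B (percentile 100). The proliferation list had 0.23 over 38 members (adjusted p = 0.00365), from medians of opposite sign, -0.26 in experiment A (percentile 0.01) and 0.54 in experiment B (percentile 100). Nuclear genes of oxidative phosphorylation had 0.23 over 41 members (adjusted p = 0.00704), from -0.11 (percentile 13.7) and 0.46 (percentile 100). Hypoxia and glycolysis genes had 0.38 over 36 members (adjusted p = 0.00821), from 0.60 in experiment A (percentile 100) and 0.037 in experiment B (percentile 24.8). By DESeq2 with the block, no member passed over all genes, and adjusted over the list alone 1 member was higher in the proliferation list and 1 in the hypoxia list. INSIG1, a feedback regulator of cholesterol synthesis, was at 147 and 120 CPM in experiment A and at 132 and 393 CPM in experiment B. P4HA1, a collagen prolyl hydroxylase gene of the hypoxia list, was at 72.0 and 255 CPM in experiment A and at 29.7 and 42.9 CPM in experiment B. The cholesterol, proliferation and oxidative phosphorylation medians turned to -0.067, -0.19 and -0.12 without shGPX4 B, and the hypoxia median turned to -0.22 without shGPX4 A. Without shControl A the adjusted p was 0.152, 0.0554, 0.185 and 0.0673, and without shControl B it was 0.438, 0.186 and 0.449 for proliferation, oxidative phosphorylation and hypoxia. The list of 15 mitochondrially encoded genes had a median of 0.47 (adjusted p = 0.314) and passed with the block (median 0.40, camera adjusted p = 0.00415, adjusted p = 0.942 with an estimated correlation). In the main test it also passed without shGPX4 A (median 1.29, adjusted p = 3.27e-07) or shControl B (3.23, 4.76e-07), and with the opposite sign without shGPX4 B (-2.58, 0.00432). These fits mix the experiments unequally, and the list's median differed between them (A minus B) by -3.50 in shControl and -3.94 in shGPX4, against 0.25 and 0.43 for shGPX4 over shControl within experiments A and B.

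In all, 7 of the 24 tested lists passed with the preset correlation, 8 with the block, and 0 with an estimated correlation under either fit. The test with an estimated correlation rests on the residual degrees of freedom, 2 without the block and 1 with it. It was not tried on simulated lists, so its 0 calls do not show that the lists were unchanged. With the block it was added after the data were seen. The planned edgeR test called 0 members of any list, over all genes or adjusted over the list alone.

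**Figure D3:**
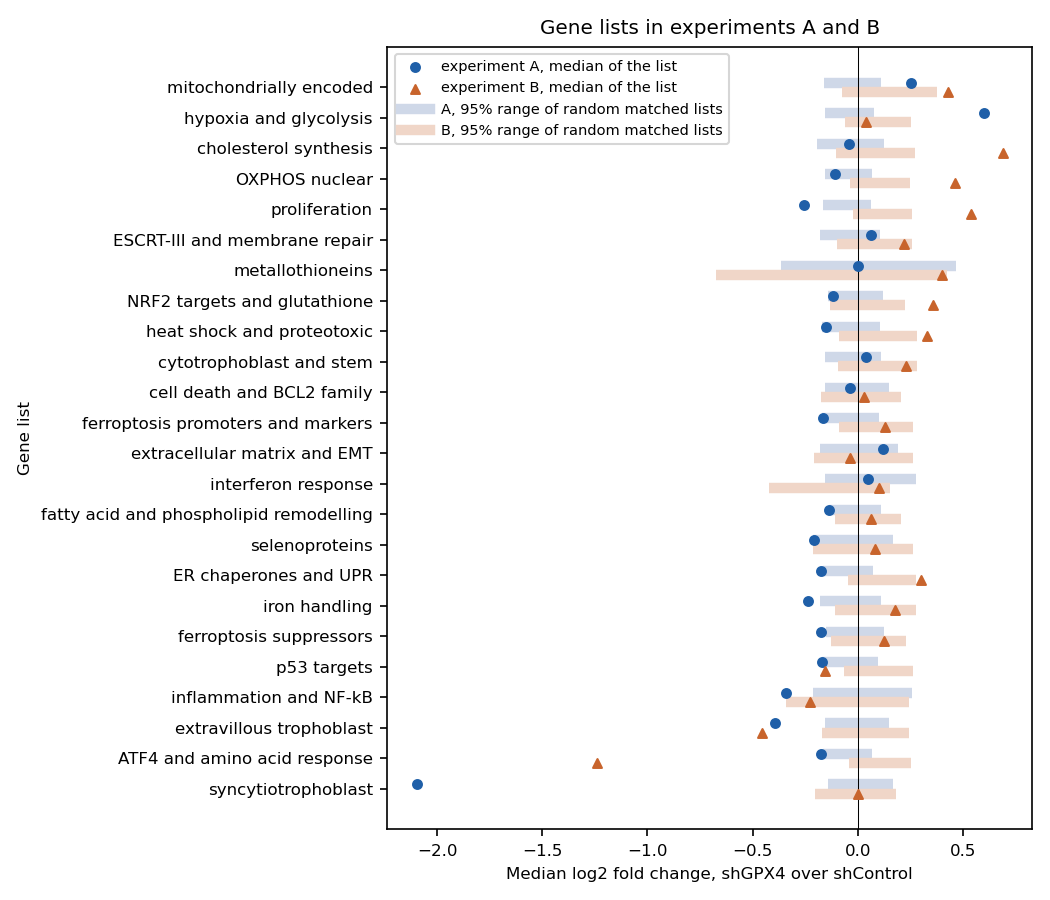
Median log2 fold change of shGPX4 over shControl of each of the 24 tested gene lists in experiment A (blue circles) and experiment B (orange triangles), with bars for the central 95% of 10000 random lists matched on expression. The syncytiotrophoblast median was -2.10 in experiment A and 0 in experiment B, the ATF4 median was -0.18 and -1.24, and the extravillous trophoblast median was -0.39 and -0.46.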

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

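The tests with DESeq2 or limma-voom and the block, camera with the block and an estimated correlation, and the tests of protein-coding genes were chosen after seeing the data. GPX4 kept its direction in each alternative run for it, and its log2 fold change ranged from -4.61 to -2.06 with 1 library left out. Adjusted over all genes it passed only by DESeq2 with the replicate block (-3.26). Counts of genes were 0 in the main test and 0 under other scalings, filters, thinning, a minimum fold of 1.5 and each left-out library. The replicate block gave 1 higher gene by edgeR, and 0 higher and 0 lower by edgeR with protein-coding genes alone. DESeq2 with the replicate block gave 32 higher and 26 lower, and with protein-coding genes alone 37 higher and 31 lower. Adjusted over the list alone, edgeR with the replicate block also passed 1 lower member each of the suppressor, promoter, cytotrophoblast, selenoprotein, heat shock, cell death and inflammation lists, 1 higher member of the inflammation and fibroblast lists and 2 lower endothelial genes. DESeq2 with the replicate block passed, adjusted over the list alone, 1 lower member each of the selenoprotein, ER chaperone, ESCRT-III, heat shock, inflammation and extracellular matrix lists, 2 lower endothelial genes, 1 higher inflammation gene and 3 higher extracellular matrix genes. The pairing changed no other call than those given here and beside the results. Scaling moved the median of all genes by under 0.1 on the log2 scale in each setting.

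The number of lists past the threshold was 7 in the main test, 1 to 8 with a library left out (1 without shControl A), and 0 with an estimated correlation, with fry and with the replicate block and an estimated correlation. The ATF4 median of -0.84 and the syncytiotrophoblast median of -0.99 lost their calls with an estimated correlation (adjusted p = 0.906) and by fry (adjusted p = 0.984). Those tests rest on 2 residual degrees of freedom and were not tried on simulated lists. A call lost by them does not show that the list was unchanged. With a library left out, the lone library of an arm is assumed to vary like the other group, and the unblocked fit sets unequal mixes of the experiments against each other, so the values include part of the difference between experiments. Medians then ranged from -1.37 to 0.0012 for ATF4, -1.82 to -0.0097 for syncytiotrophoblast, -0.22 to 0.53 for cytotrophoblast, -0.30 to 0.14 for ferroptosis suppressors and -0.15 to 0.24 for ferroptosis promoters. They ranged from -0.30 to 0.16 for iron handling, -0.12 to 0.20 for ER chaperones, -2.58 to 3.23 for mitochondrially encoded genes, -0.57 to 0.32 for selenoproteins, -0.29 to 0.16 for fatty acid genes, -0.26 to 0.14 for interferon genes and -0.16 to 1.17 for metallothioneins. They ranged from -0.22 to 0.74 for hypoxia, -0.13 to 0.20 for NRF2 targets, -0.067 to 0.77 for cholesterol synthesis, -0.19 to 0.59 for proliferation, -0.075 to 0.28 for ESCRT-III, -0.35 to 0.37 for heat shock and -0.12 to 0.49 for oxidative phosphorylation. They ranged from 0.0043 to 0.21 for cell death genes, -0.27 to -0.11 for p53 targets, -0.51 to -0.057 for inflammation, 0.0095 to 0.34 for extracellular matrix and -0.64 to -0.12 for extravillous trophoblast. The BIRC7 log2 fold change ranged from -1.65 to 6.54. Medians near 0 changed sign in other settings for fatty acid genes with DESeq2 size factors (0.0032) and no filter (0.0098), for cell death genes with limma-voom (-0.020) and the replicate block (-0.018), for ER chaperones with no filter (0.0044) and for selenoproteins after thinning (0.0086). The cause of these sign changes was not tested. The planned pseudocount alternative was not run because the deposited values are counts.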

Other observations

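Of the tests in this part, those of the control libraries, of paralogs and of the size of GPX4 loss were chosen only after the result was seen. The stress and antioxidant lists given next did not pass in the planned test of all 4 libraries, and a difference between experiments was not tested. NRF2 targets and glutathione genes had a median log2 fold change of -0.12 in experiment A and 0.36 in experiment B (joint camera adjusted p = 0.338). Heat shock genes had -0.15 and 0.33 (0.860), and HSPB8 was their 1 member past the DESeq2 threshold with the block. The heat shock list passed without shGPX4 A (median 0.37, camera adjusted p = 0.00668) and, with the opposite sign, without shGPX4 B (-0.35, 0.0261), in fits that mix the experiments unequally. ER chaperones had -0.18 and 0.30 (0.925) and iron handling genes -0.24 and 0.18 (0.925), and for both the joint median was below 0 while the test pointed up. The p53 targets had -0.17 and -0.16 (0.0641), with 0 members past the threshold by DESeq2 with the block. Of their 30 members, 21 were lower in experiment A, 18 in experiment B and 12 in both, an overlap that independent experiments could give. The list passed where genes needed a CPM of at least 1 in 2 libraries (joint median -0.21, adjusted p = 0.0401).

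Selenoproteins had medians of -0.21 and 0.084 (0.635), with GPX4 the 1 member past the DESeq2 threshold with the block. Without shGPX4 B the list's median was -0.57. These values include GPX4, the gene targeted by the hairpin, and the list was not tested without it. Fatty acid and phospholipid genes had -0.14 and 0.061 (0.884), metallothioneins 0.0022 and 0.40 (0.377), ESCRT-III and membrane repair genes 0.064 and 0.22 (0.314) and interferon genes 0.049 and 0.10 (0.709). Cell death genes had -0.035 and 0.029 (0.925), with a joint median of 0.086 and a mean of -0.077. Inflammation genes had -0.34 and -0.23 (0.234), with C3 the 1 member past the threshold with the block, and it was higher. Extracellular matrix genes had 0.12 and -0.037 (0.774), and adjusted over the list alone with the block in edgeR 3 were higher (COL5A1, TAGLN and SPARC) and 2 lower (TIMP2 and COL6A1). Too few markers of other cells passed the filter on low counts for a test, with 4 of 12 fibroblast, 4 of 12 endothelial and 2 of 16 blood cell genes. The libraries are of BeWo cells, a cell line, and the levels given next are not read as signs of other cells. The endothelial gene CDH5 was at 87.7 and 15.2 CPM in experiment A and at 75.3 and 60.5 CPM in experiment B, the fibroblast gene PDGFRA at 0.823 and 1.91 CPM and at 0.858 and 4.89 CPM, and the blood cell gene CSF1R at 120 and 198 CPM and at 187 and 166 CPM.

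The libraries split by experiment. Library totals were close, from 18926983 to 22971448 counts, so unequal depth was a weak candidate and thinning could change little. Thinning to the smallest library left the correlation of same-letter deviations at 0.817. Removing a trend on GC content and length left it at 0.791, which argues against GC or length bias as the whole cause. Replication-dependent histone genes were 7.34 log2 units higher in experiment A (median of 39), polyadenylated histone genes were 0.86 lower (-0.86, median of 12), and the difference was 8.20. A candidate explanation is that the experiments selected RNA differently, and the letter is no study group, so no biological explanation was tested. The difference in RNA classes between the experiments also enters each comparison of A with B given below.

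The syncytiotrophoblast list was lower in experiment A and had a median of 0 in experiment B. Members with no counts in either library of experiment B give exactly 0 there. Such members would also enter the differences between experiments given below. Its median in A was -2.13 after thinning, which could change little because library totals were close. Over the 24 members outside multigene families it was -1.78, which argues against shared reads as the cause. The 2 control libraries differed over the list by a median of 1.96 (A minus B), and the knockdown libraries by -0.84, with quartiles of -1.88 and 0.87 over the members. Because the knockdown libraries also differed, in the opposite direction, these values decide neither for nor against a control library that stands apart. Whether the shControl A culture had high syncytial expression or GPX4 loss lowered it in that experiment cannot be told apart with 1 library per arm.

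The ATF4 list was lower mostly in experiment B, at -1.22 after thinning, which could change little because library totals were close. The control libraries differed by a median of -1.29 (A minus B), and the knockdown libraries by -0.35, consistent with a high level of these genes in the shControl B library. The list's median was 1.06 higher in experiment A, where the GPX4 fold was larger, and with 1 library per arm this does not settle whether the fall grows with GPX4 loss. A lowering by GPX4 loss also stays open. Of the 39 members, 25 were lower in experiment A, 35 in experiment B and 24 in both. Independent experiments with those numbers could give such an overlap, so it does not decide for a shared fall. CHAC1, NUPR1 and TRIB3, which passed by DESeq2 with the block on these same libraries, were lower in both.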
